A study of Mus musculus with 4 samples.

How the data were processed

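Gene expression was measured on arrays in mouse fibroblasts that were either wild type or ablated for SIN1, a subunit of mTOR complex 2 encoded by Mapkap1. mTOR complex 2 is the kinase complex that phosphorylates AKT and related kinases. The series holds 4 arrays, 2 of wild type cells and 2 of SIN1 knock-out (SIN1 KO) cells, each with its own column. Per the labels' protocols, the cells were grown in DMEM, total RNA was taken with guanidine isothiocyanate and acid phenol, and it was labelled with biotin. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the arrays of a genotype came from separate cultures, cell lines or embryos, so the tests measure only the spread between these arrays, which may be technical.

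The deposited table holds log2 values, which the authors made with RMA (a method that corrects background, normalizes between arrays and summarises probes into probe sets), per the submitters' processing notes. The version of RMA, its background setting and the probe set definition are not given in the sources used here. That the values are on the log2 scale was taken from their range, 0.80 to 14.17, and the similar medians of the 4 columns. Values near background are partly discrete: the most frequent one, 2.28, occurs 458 times among 180404 values. No further normalization was applied. No column was left unused.

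The table names probe sets by manufacturer IDs alone, and neither it nor the gene table used here, which lists mouse genes of assembly GRCm38.p6, pairs those IDs with genes. The planned check of Mapkap1, the 36 gene lists with 775 genes fixed before the data were examined, the gene list tests and the choice between probe sets of 1 gene were therefore not analysed here. Differences are counted per probe set, and several probe sets can belong to 1 gene. The exceptions are control probe sets whose IDs carry a name. Of the 45101 probe sets, 64 were such controls and were left out of the tests. They comprised 19 for mouse sequences (18S rRNA, beta-actin, Gapdh, transferrin receptor, pyruvate carboxylase, and the B1 and B2 repeats), 18 for biotinylated hybridisation controls (BioB, BioC, BioD, Cre) and 27 for Bacillus subtilis genes (Dap, Lys, Phe, Thr, Trp).

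SIN1 KO was compared with wild type on the 45037 remaining probe sets with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 arrays per group, the fit had 2 residual degrees of freedom and a prior worth 2.38 more. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.33. The rule for named items, fixed before the data were examined, asked for called genes and members of the lists. Since it gave none, the 2 largest positive and 2 largest negative differences among probe sets whose SIN1 KO arrays both lay on one side of both wild type arrays are named, a choice made after their values were seen.

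A background level was set per array as the highest value among its 27 Bacillus subtilis control probe sets, which ranged from 1.27 to 4.27 over all arrays. On every array that value came from the same Phe probe set (3.75 to 4.27). The highest value of any other of these controls on any array was 3.64. The level thus rests on a single control. If such transcripts had been added to the RNA, the true background would be lower. A probe set was counted as present in 1 genotype alone when it was at or below that level on both arrays of the other genotype and at least 2 log2 units (4-fold) above it on both of its own. This count, its background level and its margin were chosen after the data were examined and after margins of 0, 1, 2, 3 and 4 log2 units had been looked at. Where a genotype was at background, the fold is a lower bound: the mean of the bright arrays over the mean of, per array, the higher of the background level and the probe set's own value.

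The fit was tested on simulated data made from the levels and variances of these probe sets, with 200 of 45037 changed in each of 10 runs. The variances were shuffled among probe sets, and noise was drawn independently for each. They were estimates on 2 residual degrees of freedom taken as true, so they spread more widely than the true variances would. In the real arrays the spread varied with level and was partly shared between probe sets, so the rates there may differ. It called 0% of changes of 1 log2 unit, 5.4% of 3 units, 58.2% of 6 units and 66.6% of 8 units. Of 448370 unchanged probe sets, 3 were called. Alternatives were a filter at the median level, median centring, cyclic loess, trended and robust variance priors, a 1.5-fold test (treat), a threshold of 0.01, the replicate number as a block, leaving out each array, and several added later. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.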

Results

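Expression was profiled in wild type and SIN1 KO mouse fibroblasts of the C57BL/6 strain, with 2 arrays per genotype. The labels describe the knock-out cells as having altered metabolism. The array medians were 4.28 and 4.32 in wild type and 4.23 and 4.31 in SIN1 KO on the log2 scale. Between 43.5% and 49.5% of the 45037 probe sets lay at or below the highest of the 27 Bacillus subtilis control probe sets on an array. The median of those controls was 2.04 to 2.46, below the lower quartile of the tested probe sets on each array. The level of Mapkap1, the ablated gene, was not analysed here, so the genotype labels were not checked against it.

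The comparison of SIN1 KO with wild type asked which transcripts differ when SIN1 is absent. A small set of probe sets was at background in wild type cells and clearly above it in SIN1 KO cells. This held for 34 probe sets, by factors of at least 4.66 to at least 145, with a median bound of 11.4-fold. The opposite pattern, background in SIN1 KO and at least 4-fold above it in wild type, was found for 5 probe sets, by factors of at least 4.53 to at least 11.9. At 16-fold over background or more, 8 probe sets were found in SIN1 KO alone and 0 in wild type alone. The balance between the directions depended on single arrays: the counts high in SIN1 KO and high in wild type were 77 and 143 without SIN1 KO 1, 67 and 10 without SIN1 KO 2, 109 and 57 without wild type 1, and 43 and 32 without wild type 2. None of these 39 passed limma's test over all probe sets, with adjusted p between 0.128 and 0.795 for the 34 and between 0.41 and 0.534 for the 5. Of the 34, 2 carried an ID suffix (s or x) that the manufacturer uses for probes able to bind transcripts of more than 1 gene, against 10.1% of all tested probe sets.

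**Figure D1:**
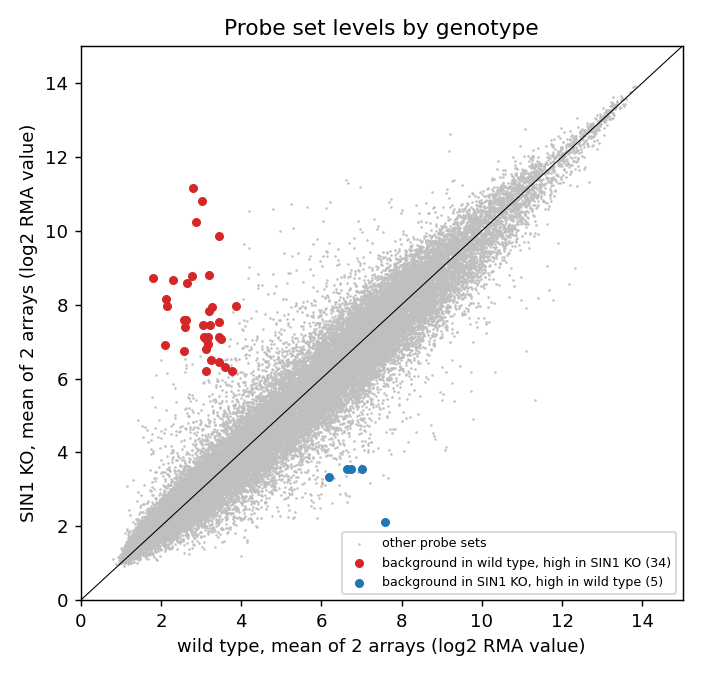
Mean log2 RMA value of each of the 45037 probe sets in wild type (horizontal axis, 2 arrays) and SIN1 KO (vertical axis, 2 arrays), with the line of equality. The 34 probe sets at background in wild type and high in SIN1 KO (red) lie far above the line, and the 5 with the opposite pattern (blue) lie below it.

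The largest positive difference was at probe set 1453572_A_AT. Its log2 value was 2.81 ± 0.49 (SD, n = 2) in wild type and 11.15 ± 0.21 (SD, n = 2) in SIN1 KO. The log2 fold change was 8.34 (SE 0.35), at least 145-fold over background, with a limma adjusted p of 0.128. Probe set 1439296_AT followed, at 3.02 ± 0.56 in wild type and 10.80 ± 0.06 in SIN1 KO (SD, n = 2). Its log2 fold change was 7.78 (SE 0.36), at least 113-fold over background, with a limma adjusted p of 0.145. For both, the difference was many times the spread between the arrays of a genotype, which their choice as the largest separated differences favours. The largest negative differences of the deposited values were less even. Probe set 1416200_AT measured 10.49 and 12.15 in the wild type arrays but 8.28 and 2.57 in the SIN1 KO arrays. Its log2 fold change of -5.89 (SE 2.03, adjusted p 0.82) rests on SIN1 KO replicate 2, whose value lay under that array's background of 4.27. With the background level in its place the difference was -5.04, at least 32.9-fold. Without that array it was -3.03, and without SIN1 KO replicate 1 it was -8.75. Probe set 1460465_AT measured 7.58 ± 0.15 (SD, n = 2) in wild type and 2.12 ± 0.81 (SD, n = 2) in SIN1 KO. That is at least 11.9-fold lower than wild type, with a log2 fold change of -5.46 (SE 0.46, adjusted p 0.427).

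Over all probe sets, 0 were higher and 0 lower in SIN1 KO past the adjusted threshold in limma's test, and the lowest adjusted p was 0.128. At an unadjusted threshold of 0.05, 1350 were higher and 1159 lower, 2509 in all, where 2252 would be expected with no difference at all. Neither the total nor the direction was stable: the counts higher and lower were 1522 and 2351 without wild type 1, 516 and 742 without wild type 2, 1444 and 1708 without SIN1 KO 1, and 690 and 429 without SIN1 KO 2. With the replicate number as a block they were 663 and 630, and with the crossed pairing as a block 2899 and 3473. The crossed pairing was chosen after these values were seen and leaves the least residual spread, which raises its counts. The split that joins wild type 1 with SIN1 KO 2, against the other arrays, gave 3621 probe sets at that threshold, more than the genotype split. When only the 22519 probe sets at or above the median level were tested, 5 passed, each higher in SIN1 KO, with an adjusted p of 0.0231. Their fitted log2 fold changes were 5.99 to 8.34, but both wild type arrays were at background, and against that background they were at least 25.7-fold to at least 145-fold higher. All 5 belong to the 34 above, and 1453572_A_AT and 1439296_AT are among them. Arrays scaled to the hybridisation controls instead gave 5381 higher and 370 lower at the unadjusted threshold and 0 past the adjusted one, with the median of all probe sets shifted from 0.04 to 0.36.

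Mouse control probe sets gave values that can be tied to transcripts by the names in their IDs. Transferrin receptor, which takes up transferrin-bound iron, was 7.35 ± 1.28 in wild type and 6.36 ± 0.39 in SIN1 KO (SD, n = 2, mean of 3 probe sets). Wild type replicate 2 alone set that difference: it stood at 8.26, against 6.45 in wild type replicate 1 and 6.63 and 6.08 in the SIN1 KO arrays. Without it the difference of -0.996 became -0.09. Pyruvate carboxylase, the mitochondrial enzyme that makes oxaloacetate from pyruvate, was 5.56 ± 0.07 in wild type and 5.66 ± 0.82 in SIN1 KO (SD, n = 2, mean of 4 probe sets). Its SIN1 KO arrays, at 5.07 and 6.24, lay on either side of both wild type arrays, and the difference of 0.10 was 0.68 without SIN1 KO 1 and -0.48 without SIN1 KO 2. Gapdh, a glycolytic enzyme, differed by -0.08, beta-actin by -0.10 and 18S rRNA by -0.06, and these small differences turned positive, to 0.24, 0.22 and 0.26, when arrays were scaled to the hybridisation controls. Without wild type 1 or without SIN1 KO 1, Gapdh (0.02 and 0.04) and beta-actin (0.04 and 0.05) were also positive. The probe set for the B1 repeat, a short interspersed element present in many transcripts, was 10.90 ± 0.07 in wild type and 11.83 ± 0.53 in SIN1 KO (SD, n = 2), while the B2 repeat differed by -0.04, which turned to 0.28 under the same scaling. The B1 difference of 0.93 was between 0.85 and 1.25 under the 3 other scalings, 0.56 without SIN1 KO 2 and 1.30 without SIN1 KO 1. None of the 19 mouse control probe sets passed limma's test adjusted over the list alone (lowest adjusted p 0.984).

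**Figure D2:**
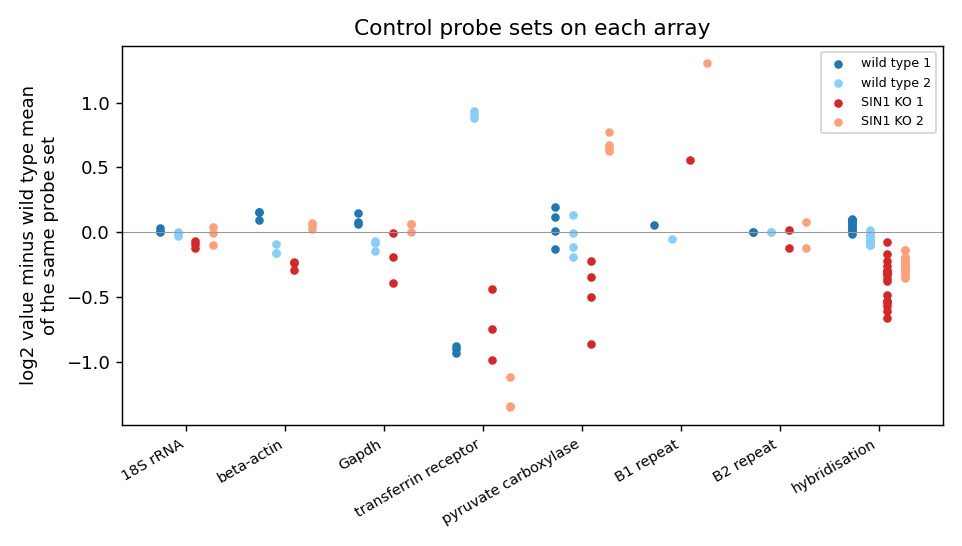
Log2 value of each mouse and hybridisation control probe set on each array, minus the wild type mean of the same probe set (vertical axis), by class of control (horizontal axis); each point is 1 probe set on 1 array. Transferrin receptor is high on wild type 2 alone, the SIN1 KO arrays bracket the wild type arrays for pyruvate carboxylase, and the B1 repeat and the hybridisation controls separate the genotypes.

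The hybridisation controls are bacterial and phage transcripts added to each sample before it is put on the array. All 18 were lower on both SIN1 KO arrays than on both wild type arrays, by 0.32 on the log2 scale on average (11.79 ± 0.09 in wild type and 11.47 ± 0.09 in SIN1 KO, SD, n = 2). None passed limma's test adjusted over the list alone (lowest adjusted p 0.393).

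The closest and the most distant arrays were both pairs of different genotypes. Across probe sets, which are not independent replicates, the closest pair was wild type 1 with SIN1 KO 1 (Pearson r = 0.971). The wild type arrays correlated with r = 0.955 and the SIN1 KO arrays with r = 0.958. The most distant pair was wild type 2 with SIN1 KO 2 (r = 0.904), and 13232 probe sets differed by at least 1 log2 unit between them, against 3607 between wild type 1 and SIN1 KO 1. The difference between SIN1 KO 1 and wild type 1 did not resemble that between SIN1 KO 2 and wild type 2 (r = 0.009 across probe sets), whereas the difference between SIN1 KO 1 and wild type 2 correlated with that between SIN1 KO 2 and wild type 1 (r = 0.421). The first principal component held 63.8% of the variance and set wild type 2 at 124 against SIN1 KO 2 at -120, with wild type 1 at -1.51 and SIN1 KO 1 at -3.12. The genotypes were apart on the second component only for the number 1 arrays, at -76.5 for wild type 1 and 54.5 for SIN1 KO 1, and the number 2 arrays lay together between them.

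**Figure D3:**
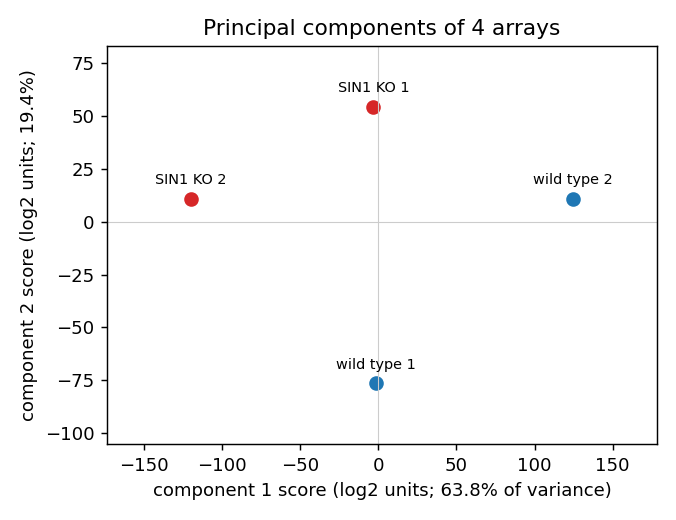
Scores of the 4 arrays on the first component (horizontal axis, 63.8% of variance) and the second (vertical axis, 19.4%), in log2 units over 45037 probe sets; blue points are wild type and red points SIN1 KO. Wild type 2 and SIN1 KO 2 lie at the ends of the first component, and wild type 1 and SIN1 KO 1 lie near its middle.

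The spread between numbered pairs was also seen in the probe sets that cross background. Between the number 1 arrays alone, 106 probe sets were at background in wild type and high in SIN1 KO, and 57 the reverse. Between the number 2 arrays alone the counts were 229 and 585. Of the 585 high in wild type 2 and at background in SIN1 KO 2, 5 had the same pattern in the number 1 arrays, and 8 had the opposite one. Of the 229 high in SIN1 KO 2 and at background in wild type 2, 34 had the same pattern in the number 1 arrays, and 9 had the opposite one.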

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

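The tests of array splits, array swaps, dim probe sets and RNA integrity, the second test of mixing and the reference and interval of that test were chosen only after results were seen; the loess test and the first test of mixing were set before, but the interval for the latter was added after.

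The control probe set for the B1 repeat, which no comparison between probe sets used, was 0.93 log2 units higher in SIN1 KO than in wild type, with both SIN1 KO arrays (11.46 and 12.21) at least 0.5 above both wild type arrays (10.95 and 10.85). The difference was 0.56 without SIN1 KO replicate 2. The minimum gap of 0.5 that singled it out was chosen after the values were seen, and its own gap is close to it. The probe set did not pass limma's test over the list of mouse controls (lowest adjusted p 0.984).

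A first pattern is the 39 probe sets at background in 1 genotype and high in the other, 34 of them high in SIN1 KO. The 4 arrays can be split 2 against 2 in 3 ways, too few for a share under 0.05. The genotype split gave 39 such probe sets and the highest other split 17. Only the genotype split itself, 1 of the 3, gave 39. A swap of same-numbered arrays between the groups cannot be told apart from true labels. Of the probe sets chosen on the number 2 arrays, 9 of the 229 high in SIN1 KO 2 and 8 of the 585 high in wild type 2 were reversed in the number 1 arrays, but these are the probe sets that make up the 17 of the other split, so they add nothing to the count of splits. Loss of SIN1 stays open as an explanation for the 34, and so does any other difference between the cell populations, since the labels name no independent lines.

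A second pattern is the first principal component, which sets wild type 2 against SIN1 KO 2. An intensity-dependent trend left in the deposited values is argued against, since 64.1% of the variance stayed on that component after cyclic loess. RMA had already normalized these values, so the test cannot speak to a distortion made by that step. Noise of probe sets below the median level is argued against too, since the brighter probe sets (at or above that level) put 67.4% there. That outcome could be foreseen from the spread by level, which had been seen. The SD of SIN1 KO 2 minus wild type 2 was 0.32 in decile 1 by mean level and 1.57 in decile 7. The median level, 4.31, lay just above the background levels of the arrays (3.75 to 4.27). Noise of probe sets close above background was therefore not tested. Wild type RNA mixed into SIN1 KO replicate 1 is argued against as the only source of that component. It would leave wild type 1 beside wild type 2, but these scored -1.51 and 124 there. It would also make SIN1 KO 1 minus wild type 1 resemble SIN1 KO 2 minus wild type 2, unless little SIN1 KO RNA was left in the mixture. The r of 0.009 across probe sets therefore cannot decide, and it partly restates those scores. Whether some wild type RNA in SIN1 KO replicate 1 contributed stays open after 2 tests. Such a mixture would put SIN1 KO 1 a fixed distance under wild type for the 143 probe sets high in both wild type arrays and at background in SIN1 KO 2. The SD of that distance was 1.12, against 1.02 between the wild type arrays, a ratio of 1.09 (95% bootstrap interval 0.889 to 1.36), which lies between the 1 that a mixture would allow at most and the 1.5 set before as the bound against it. The distance was from the mean of 2 wild type arrays, while the reference set single arrays against each other. A mean varies less than a single array, so a mixture could give a ratio under 1. Because that test did not decide, a second one took the 77 probe sets high in SIN1 KO 2 and at background in both wild type arrays. The SD of SIN1 KO 1 minus SIN1 KO 2 was 2.18 there, against 1.33 for wild type 1 minus wild type 2 over the 57 probe sets high in wild type 2 and at background in both SIN1 KO arrays, which were chosen on 1 array in the same way. The ratio of 1.64 passed the bound, but its 95% bootstrap interval, 1.29 to 2.16, includes it. Both intervals reflect the spread over probe sets on these arrays, not between arrays, and probe sets are not independent replicates. RNA integrity stays open: 0 of 4 mRNA controls had wild type 2 and SIN1 KO 2 at opposite extremes of the 3' minus 5' difference, but 4 transcripts going both ways do not decide it. A difference in the state of the cultures is open and was not tested, and no biological explanation was tested, because the design names no factor besides genotype.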

How the results depend on the processing

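The alternatives for the background counts and the controls, the scaling to hybridisation controls, the crossed pairing and the unadjusted counts were chosen only after results were seen. The counts past the adjusted threshold were 0 in both directions under median centring, cyclic loess and trended or robust priors. Treat and the stricter threshold could only give 0. With fewer residual degrees of freedom, the replicate block (0) and left-out arrays tested little. A group's lone array was assumed to vary like the other genotype's. The filter at the median level gave 5 higher (5 of them at least 2-fold) and 0 lower. At the unadjusted threshold the filter left 705 higher and 619 lower, with fewer probe sets tested. The replicate block gave 663 and 630. Same-numbered arrays deviated in opposite directions (r = -0.415), and the crossed pairing as a block, added for that reason, gave 2899 and 3473 (0 past the adjusted threshold). Scaling to the hybridisation controls gave 5381 and 370, since it shifts every probe set the same way. Leaving out 1 array gave 516 to 1522 higher and 429 to 2351 lower: 1522 and 2351 without wild type 1, 516 and 742 without wild type 2, 1444 and 1708 without SIN1 KO 1, and 690 and 429 without SIN1 KO 2. The counts at background in wild type and high in SIN1 KO, and the reverse, were 34 and 5 under each other scaling, but median centring and scaling to the hybridisation controls shift a value and its array's background alike and could not change them, so cyclic loess alone was a test. A margin of 0 gave 421 and 280, of 1 gave 66 and 37, of 3 gave 19 and 1 and of 4 gave 8 and 0, and the 95th percentile as background 23 and 8. The number 1 arrays alone gave 106 and 57, the number 2 arrays alone 229 and 585, and leaving out 1 array, which by construction loosens the rule, 43 to 109 and 10 to 143 (77 and 143 without SIN1 KO 1). Of the 48 alternative values of the 4 named probe sets, 46 stayed short of the threshold and 2 passed it under the filter. Left-out arrays, priors and blocks could not test their direction, which their choice fixed. Of 23 control differences under other scalings, 16 moved by less than the spread between replicates and 7 by more. The alternatives on Mapkap1, gene lists and probe sets of 1 gene were not run, because no table used here pairs probe sets with genes. In simulation with 2 arrays per group, 0% of changes of 1 log2 unit and 5.4% of 3 units were called, so most were missed. Noise there was independent between probe sets, and variances estimated from few arrays were taken as true, so the rates in the real arrays may differ. Signal over background limits the folds: 43.5% to 49.5% of probe sets were at or below background on an array.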

Other observations

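All counts here were chosen after the data were examined. Of the 143 probe sets high in both wild type arrays and at background in SIN1 KO 2, 138 were above background in SIN1 KO 1, and 78 followed the order wild type 2, wild type 1, SIN1 KO 1, SIN1 KO 2 from high to low. Wild type 2 was above wild type 1 in 105 of them. SIN1 KO 1 lay 0.95 log2 units below the wild type mean at the median. These probe sets were chosen for being high in both wild type arrays and low in SIN1 KO 2, with no condition on SIN1 KO 1. The choice put SIN1 KO 2 under both wild type arrays and favoured SIN1 KO 1 lying between them and SIN1 KO 2.

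The spread between the number 2 arrays was largest at intermediate levels. The SD of SIN1 KO 2 minus wild type 2 was 1.57 log2 units in decile 7 of probe sets by mean level (mean level 5.71), 0.32 in decile 1 and 1.18 in decile 10. The SD of SIN1 KO 1 minus wild type 1 was 0.86, 0.28 and 0.56 in the same deciles.

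The split that joins wild type 1 with SIN1 KO 2 and wild type 2 with SIN1 KO 1 gave 5094 probe sets with a mean difference of at least 1 log2 unit, more than the 4428 of the genotype split, and 3621 at the unadjusted threshold, more than its 2509. Of the 4428, 1800 were higher and 2628 lower in SIN1 KO. Gaps of at least 1 log2 unit between the arrays of one side and those of the other were found for 712 probe sets in the genotype split. The split that joins wild type 1 with SIN1 KO 2 gave nearly as many, 656. Gaps of at least 3 log2 units were more frequent for the genotype split. They were found for 54 probe sets there (48 with SIN1 KO higher), against 21 for the split that joins wild type 1 with SIN1 KO 2.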
